A study of Mus musculus with 12 samples.

How the data were processed

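The measurements were RNA-seq profiles of mouse CD1 embryos (a stock of outbred mice) at the morula, early blastocyst and late blastocyst stages. Per the labels' protocols, GFP mRNA was injected into zygotes together with the siRNA, and libraries were made with the SMARTer Ultra Low Input kit, which amplifies full-length cDNA from small amounts of RNA, and the NEBNext Ultra DNA kit. Neither label states strand, so reads of a gene and of an antisense partner were taken as not separable. The number of embryos in each library is not given in the sources used here.

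The submitters' processing notes list HISAT2 version 2.1.0, Cufflinks, HTSeq and edgeR and the mouse genome build mm10, with no role or order. The authors deposited 1 table of 43472 genes for 12 libraries, whose columns are headed RPKM per the file headers. The values do not have that form. In every column each value was a whole multiple of 1 step, the same step for genes of every length (100.0% of values were whole within a tolerance of 0.01 reads), and every column summed to 279173.646. The deposited values are therefore CPM (reads of a gene per 1e6 reads) divided by a constant of 3.582, not divided by each gene's length, and levels below are given in CPM after multiplying by that constant. The design fixed beforehand had assumed RPKM. The planned test suits CPM as well and was kept, with its pseudocount and filter read in the deposited unit. The steps gave back whole reads, 10524640 to 13770264 per library, so a count of 3 reads, the limit that a count of 0 allows, corresponded to 0.218 to 0.285 CPM. This limit covers counting error only, because amplified reads without molecular identifiers are not independent molecules.

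The gene names in the deposited table include 27 that a spreadsheet had turned into dates, 2 that occur in more than 1 place and 12 that end in a semicolon, and these were kept as separate features under their deposited names. Of all names, 39368 (90.6%) matched 1 gene of GENCODE release M21, built on the same mouse assembly, which gave the coordinates (1-based) and gene types. All 13 mitochondrially encoded genes were listed at 0 in every library. Libraries of 1 group were compared over genes before averaging. The chi-square statistic per gene was 17.0 to 41.1, above the noise of read sampling, so no pair of libraries was merged. Amplified reads can exceed that noise even between libraries of 1 sample, so this does not show that the 2 libraries came from separate samples.

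Differential expression was tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(value + 1) in the deposited unit, a pseudocount of 3.582 CPM, over the 10751 genes with a mean of at least 1 deposited unit. Log2 changes are on that scale, which understates the change of low genes. All 12 libraries entered 1 fit with 6 group means, 6 residual degrees of freedom and 7.55 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The comparisons were Tdgf1 siRNA minus control within each stage, the average of these 3 differences, their differences between stages (a moderated F test over all 3 stages), and the later minus the earlier stage in controls. Tdgf1 itself was also tested by exact permutation of the labels within stages and by exact sign flips of pairs. Plots and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

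The labels number the libraries of each group 1 and 2. Deviations of same-numbered control and Tdgf1 siRNA libraries from their group means correlated at 0.458 at morula, 0.593 at early blastocyst and 0.101 at late blastocyst. All 3 exceed 0.1, so the numbers were taken to pair libraries within a stage, from the data and not from a stated shared day or litter, and the late blastocyst value only just does so. Control libraries of neighbouring stages correlated at 0.006 (morula with early blastocyst) and 0.138 (early with late blastocyst). Numbers were not taken to pair stages, although 0.138 also exceeds 0.1 and is above the late blastocyst value of 0.101. The pairing at late blastocyst, and what the block gives there, is therefore uncertain. The fit with stage-and-number pairs as a block had 3 residual and 13.6 prior degrees of freedom. It is given beside a result where it changed the call or moved a count by over 1.5 times.

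A set of 20 gene lists was fixed before the data were examined: epiblast and pluripotency, primitive endoderm, trophectoderm, Nodal and TGF-beta signalling, FGF and ERK signalling, Wnt signalling, Hippo and Notch signalling, maternal oocyte transcripts, 2-cell stage transcripts, p53 targets and apoptosis, stress and unfolded protein response, interferon and double-stranded RNA response, cell cycle G2/M, glycolysis, sterol synthesis, DNA methylation machinery, mitochondrially encoded, cumulus and granulosa cells, blood and reproductive tract, and sex-linked composition. The 16 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With an estimated correlation, the stricter test below, 0 lists passed in any comparison. These include comparisons of stages in which most members of a list rose. A call lost in that test therefore does not show that a list was unchanged. Camera asks whether the genes of a list rank higher or lower than other genes. The p-value of fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. The rule for named genes was also fixed beforehand: Tdgf1; in each comparison the 10 largest changes in each direction among genes past the threshold whose groups do not overlap, (for the average, those with 1 direction in all 3 stages; for the test over stages, the 10 with the smallest p), filled up to 5 per direction, where fewer pass, with the smallest unadjusted p among non-overlapping genes with a mean of at least 5 deposited units in the higher group; in each list up to 4 members past the threshold, otherwise the 2 with the largest change; and a set of lineage and signalling genes (Nanog, Sox2, Fgf4, Pou5f1, Gata6, Gata4, Sox17, Pdgfra, Cdx2, Gata3, Eomes, Nodal, Lefty1, Lefty2, Dusp4 and Xist). Genes named outside that rule are marked as chosen after their values were seen.

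Further settings fixed beforehand were a pseudocount of 0.1, no filter, a filter at a mean of 5 deposited units, quantile normalization, median-of-ratios scaling, the pair block, library weights, each library left out in turn, and fits of 1 stage or of the controls alone. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test, with and without the pair block) and DESeq2 1.42.0 on the recovered reads, and the average without the early blastocyst stage.

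The method was tested on simulated data of the same 10751 genes with 50 genes changed at each of 4 fold sizes. With independent libraries, limma recovered 64% of genes changed 2-fold and 98% of those changed 4-fold at morula, 62% and 96% at early blastocyst, and 48% and 98% at late blastocyst, and for the average 98% and 100.0%. Where simulated pairs shared their deviations, the fit without the block recovered 4%, 0% and 8% of 2-fold changes at the 3 stages in turn and 56%, 54% and 62% of 3-fold changes, and 86% of 2-fold changes for the average. The blocked fit then recovered 40%, 44% and 52% of 2-fold changes at the 3 stages. These shares may be too low for the real data, where pairs correlated only weakly at late blastocyst. The simulated deviations were equally large at every stage and were added to a spread that already held the differences between pairs. With nothing changed and pairs simulated in this way, the blocked fit gave at least 1 false call in 35% of 20 simulations at morula, 40% at early blastocyst, 50% at late blastocyst and 35% for the average, with at most 7, 5, 7 and 4 calls. Across 20 simulations with 200 genes changed, false calls averaged 6.11% to 10.9% of the blocked fit's calls, and with independent libraries 6.07% to 9.83% of the calls without the block, above the nominal 5%. Where pairs shared deviations, the fit without the block had 3.10% false calls at morula, 2.21% at early blastocyst, 5.99% at late blastocyst and 1.61% for the average. Of 6 shifted lists, 5 or 6 were recovered in each comparison and no unshifted list was called. All members of a shifted list moved by the same amount, larger than most list means called below in siRNA comparisons. The simulated lists also held more genes than most tested lists. Recovery of smaller shifts or of shorter lists was not measured. Genes were simulated independently of each other, so this does not cover false calls from genes that move together. Other splits of the real libraries called up to 6 lists, as given below. GFP and sequences outside the deposited gene table were not analysed here.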

Results

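The RNA content of preimplantation mouse embryos was profiled after injection of zygotes with an siRNA against Tdgf1 or a negative control siRNA. Tdgf1 encodes Cripto, a membrane-anchored co-receptor for Nodal and related ligands. Embryos were collected at the morula stage, before the first lineages have separated, at the early blastocyst stage, when the trophectoderm surrounds an inner cell mass, and at the late blastocyst stage, when the inner cell mass is parting into epiblast and primitive endoderm. Each of the 6 groups holds 2 libraries (n = 2). Nothing in the labels says whether the 2 came from separate embryos, cultures or injections, so the p-values measure only the spread between these samples, which may be technical. Levels are mean CPM ± SD with the Tdgf1 siRNA group first unless stated, log2 changes carry a standard error (SE) where they describe a gene, and adjusted p-values are from limma unless another tool is named.

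Tdgf1 RNA was lower in Tdgf1 siRNA embryos in 5 of 6 same-numbered pairs. The gene lies on chromosome 9 (110939603 to 110946158, minus strand, GRCm38) and was covered by 113 to 1097 reads per library. At morula its level was 13.3 ± 3.22 against 26.4 ± 4.26 CPM (50.2% of control), at early blastocyst 12.3 ± 4.21 against 17.4 ± 6.13 CPM (70.4%) and at late blastocyst 60.1 ± 15.1 against 90.9 ± 8.94 CPM (66.1%), n = 2 each. The exception was the library labelled early blastocyst Tdgf1 siRNA replicate 2, at 15.2 CPM against 13.1 CPM in control replicate 2 (116.5%), while the first pair of that stage stood at 9.27 against 21.7 CPM (42.6%). At late blastocyst pair 1 stood at 50.9% of control and pair 2 at 83.6%. The mean log2 change over stages was -0.61, with an exact two-sided p = 0.0185 over 216 assignments of labels within stages (smallest possible 0.00926) and p = 0.0625 over 64 sign flips of pairs (smallest possible 0.0312). Among all genes, Tdgf1 did not pass limma at any stage (log2 change -0.84 at morula, -0.40 at early and -0.59 at late blastocyst). The related copy Tdgf1-ps1 reached at most 3.71 CPM. Nodal and its targets Lefty1 and Lefty2 lay below the filter, at means of 0.390, 0.508 and 1.46 CPM over all libraries and at most 1.94, 2.21 and 11.7 CPM in 1 library.

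**Figure D1:**
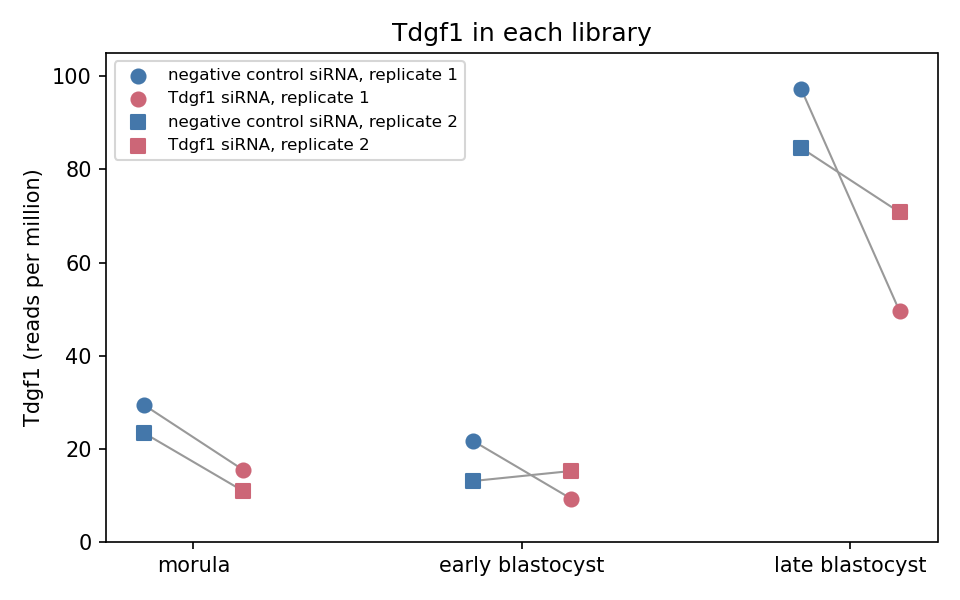
Tdgf1 level in each library by stage and siRNA. Same-numbered libraries are joined.

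Stage set most of the differences between libraries. The first principal component held 70.8% of the variance and ordered the embryos from morula to late blastocyst, and the second held 11.2%. At early blastocyst the 2 replicate numbers stood further apart than the 2 siRNAs: replicate 1 scored 6.01 (control) and 1.20 (Tdgf1 siRNA), and replicate 2 scored -20.2 and -15.9, nearer to the morulae. At late blastocyst, Tdgf1 siRNA replicate 1 scored 46.9, below the 56.5 to 60.5 of the other 3 libraries. Markers of other cells were scarce. Of the cumulus and granulosa cell list only Serpine2 and Amhr2 passed the filter, of the blood and reproductive tract list only Cd74, Vim and Pecam1, and of the 2-cell list only Sp110, Arg2 and B020004J07Rik, so these lists were not tested. No member of the 3 lists passed in an siRNA comparison. The mitochondrially encoded list could not be tested either, because its 13 genes are listed at 0.

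**Figure D2:**
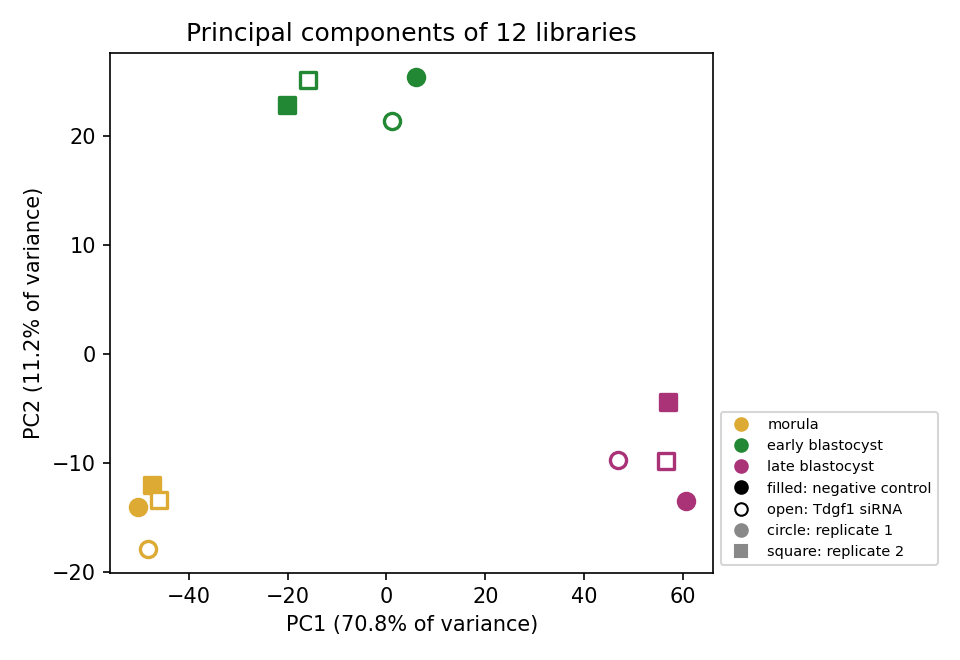
First 2 principal components of the 12 libraries. Colour gives the stage, filled marks are control and open marks Tdgf1 siRNA, and shape gives the replicate number.

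At morula, the list of p53 targets, genes that act in cell cycle arrest and cell death, ranked higher in Tdgf1 siRNA embryos and that of the G2 and M phases slightly lower, with 0 single members past the threshold. Both list calls were lost in the stricter test (adjusted p = 0.879 with an estimated correlation), and the p53 mean went from 0.26 to 0.05 without Tdgf1 siRNA replicate 2. Plk2 stood at 24.1 ± 17.1 against 12.5 ± 0.106 CPM and Eda2r at 33.5 ± 17.7 against 19.9 ± 0.812 CPM, n = 2 each. Among cell cycle genes, Aurkb stood at 51.9 ± 15.2 against 64.0 ± 2.42 CPM and Tpx2 at 187 ± 11.1 against 229 ± 26.1 CPM. The lineage regulators gave Nanog at 345 ± 82.8 against 455 ± 150 CPM (log2 change -0.38, SE 0.24), Pou5f1 at 279 ± 19.8 against 247 ± 19.8 CPM, Gata6 at 424 ± 45.6 against 405 ± 39.0 CPM and Cdx2 at 60.3 ± 20.8 against 53.8 ± 2.18 CPM, none of which passed.

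With limma, 0 of 10751 genes passed at morula, with 194 at an unadjusted p under 0.05. edgeR gave 0 genes (265 unadjusted) and DESeq2 0. Among the smallest unadjusted p-values were those of Gm17167 (58.5 ± 4.34 against 31.2 ± 5.06 CPM), Mtr (27.1 ± 0.942 against 13.4 ± 1.30 CPM) and Ankrd6 (11.96 ± 0.562 against 22.9 ± 2.22 CPM). With pairs as a block 5 genes passed on the higher side (663 unadjusted), within the at most 7 calls that this fit gave in simulations with nothing changed (at least 1 call in 35% of them): Btg1 (103 ± 14.1 against 46.8 ± 35.3 CPM), Klf6 (42.7 ± 3.56 against 20.7 ± 6.59 CPM), the heme oxygenase gene Hmox1 (37.7 ± 23.2 against 14.8 ± 7.07 CPM) and the trophectoderm genes Dppa1 (24.1 ± 8.98 against 9.86 ± 2.72 CPM) and Atp1b1 (42.2 ± 0.816 against 23.4 ± 1.90 CPM), each with adjusted p = 0.0446. Klf6 was chosen after its values were seen. Without pair 1 the blocked fit gave 4 genes and without pair 2 it gave 3. With edgeR and the block, 1 gene passed, Rpl17-ps5 (log2 change -5.97, adjusted p = 0.0201), also chosen after its values were seen. The groups did not overlap for 2953 genes (27.5%). Chance gives 33.3% for libraries that are not paired, here and for the later siRNA comparisons, and deviations shared within pairs lower that share by an amount not computed here.

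Of the 16 lists tested at morula, 2 passed. The p53 list was higher (adjusted p = 0.000235, median log2 change 0.31; adjusted p = 0.879 with an estimated correlation), with 18 of 21 members at positive values. Over all genes 0 members rose, 0 fell and 21 did not pass, and adjusted over the list alone 0 passed. The call was lost without control replicate 2 (mean 0.17 in place of 0.26, adjusted p = 0.317) and without Tdgf1 siRNA replicate 2 (0.05, adjusted p = 0.874), and the mean was 0.48 without Tdgf1 siRNA replicate 1. The cell cycle G2/M list was lower (adjusted p = 0.0262, median -0.04, mean -0.09; adjusted p = 0.879 with an estimated correlation), with 21 of 28 members at negative values, 0 past the threshold over all genes and 0 adjusted over the list alone. That call was lost with quantile normalization (adjusted p = 0.0840), without control replicate 1 (mean 0.02, adjusted p = 0.859) and without Tdgf1 siRNA replicate 2 (-0.03, adjusted p = 0.562), and the mean was -0.20 without control replicate 2 and -0.14 without Tdgf1 siRNA replicate 1. The other 14 lists, each with 0 members past the threshold over all genes and 0 adjusted over the list alone, had adjusted p = 0.414 to 0.911. Of these, trophectoderm and sterol synthesis were higher with the block (adjusted p = 0.0139 each, against 0.414; adjusted p = 0.873 each with the block and an estimated correlation). With the block, the members that passed adjusted over the list alone were 6 for trophectoderm, 3 for stress, 1 for p53 and 1 for glycolysis. The Nodal and maternal lists ranked lower while their medians were 0.01 and 0.06. With fry, every list had adjusted p = 0.979.

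At early blastocyst, when the cavity has formed, the epiblast and FGF lists ranked higher in Tdgf1 siRNA embryos and the cell cycle list lower, with 0 single members past the threshold. All 3 list calls were lost in the stricter test (adjusted p = 0.283 with an estimated correlation). The pluripotency regulators Sox2 and Esrrb stood at 17.6 ± 10.1 against 10.5 ± 8.999 CPM and 17.4 ± 5.61 against 11.4 ± 4.05 CPM, n = 2 each. The ERK feedback regulator Spry2 stood at 16.2 ± 1.63 against 8.83 ± 1.19 CPM and Etv5 at 34.7 ± 5.07 against 24.9 ± 6.21 CPM. Cenpf, a kinetochore gene, stood at 85.5 ± 40.9 against 114 ± 22.1 CPM and Hmmr at 92.4 ± 18.5 against 125 ± 1.72 CPM. These directions rest in part on the library labelled early blastocyst Tdgf1 siRNA replicate 2, in which Tdgf1 was not below its control.

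With limma, 0 genes passed at early blastocyst (112 unadjusted), edgeR gave 0 (144 unadjusted) and DESeq2 0. Dap stood at 136 ± 6.51 against 89.9 ± 2.49 CPM, Pramel5 at 523 ± 12.3 against 384 ± 13.7 CPM and Arhgap5 at 112 ± 6.71 against 159 ± 8.35 CPM, and none passed. With pairs as a block 5 genes passed on the lower side (491 unadjusted), as many as the at most 5 calls of simulations with nothing changed (at least 1 call in 40% of them), and edgeR with the block gave the same 5. Of these, 4 are unprocessed pseudogenes in 1 cluster on chromosome 11 (60591721 to 60657857, minus strand, GRCm38): Gm12621 (27.0 ± 13.0 against 64.0 ± 20.4 CPM, adjusted p = 0.0127), Gm12619 (51.1 ± 20.5 against 110.2 ± 50.7 CPM, adjusted p = 0.0193), Gm12627 (34.5 ± 9.28 against 70.4 ± 19.5 CPM) and Gm12625 (19.4 ± 6.89 against 43.8 ± 12.5 CPM), the last pair at adjusted p = 0.0214. The other was Tpm3-rs7 (50.1 ± 37.7 against 136 ± 98.1 CPM, adjusted p = 0.0128). Gm12627 and Tpm3-rs7 were chosen after their values were seen. The blocked fit gave 0 genes without pair 1 and 6 without pair 2. The groups did not overlap for 2084 genes (19.4%), where chance gives 33.3% without pairing.

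Of the 16 lists, 3 passed at early blastocyst, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. The epiblast list was higher (adjusted p = 0.0110, median 0.13, 17 of 23 members positive; adjusted p = 0.283 with an estimated correlation), and its call was lost without control replicate 1 (mean 0.16 in place of 0.15, adjusted p = 0.439) and without the library labelled early blastocyst Tdgf1 siRNA replicate 2 (0.17, adjusted p = 0.421), so the mean did not depend on them. The FGF and ERK list was higher (adjusted p = 0.00674, median 0.17, mean 0.18, 15 of 18 positive; adjusted p = 0.283 with an estimated correlation). That call was lost with no filter (mean 0.08, adjusted p = 0.197), without Tdgf1 siRNA replicate 1 (0.08, adjusted p = 0.135), without control replicate 2 (0.05, adjusted p = 0.180) and without the library labelled early blastocyst Tdgf1 siRNA replicate 2 (0.28, adjusted p = 0.0928), and the mean was 0.31 without control replicate 1. The cell cycle G2/M list was lower (adjusted p = 0.000133, median -0.11, 24 of 28 negative; adjusted p = 0.283 with an estimated correlation), and its call was lost without Tdgf1 siRNA replicate 1 (adjusted p = 0.0942) and without control replicate 2 (adjusted p = 0.166), each with a mean of -0.14 as with all libraries. The other 13 lists had adjusted p = 0.157 to 0.941, with 0 members past the threshold over all genes and 0 adjusted over the list alone (with the block, 1 of the stress list). Among these, trophectoderm ranked lower with a median of 0.03, sex-linked composition lower with a median of 0.05 and DNA methylation higher with a median of -0.01. Trophectoderm was called lower without control replicate 2 (mean -0.34, adjusted p = 0.00321).

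At late blastocyst, the p53 target list ranked higher in Tdgf1 siRNA embryos and the primitive endoderm, trophectoderm, stress response and glycolysis lists lower, with 0 single members past the threshold over all genes. All 5 list calls were lost in the stricter test (adjusted p = 0.298 to 0.663 with an estimated correlation), and the stress list was split, with 10 members positive and 11 negative. Without Tdgf1 siRNA replicate 1 the primitive endoderm mean changed sign and that of trophectoderm nearly vanished, as given below. In that library Tdgf1 stood at 50.9% of its same-numbered control, against 83.6% for replicate 2. Leaving replicate 1 out therefore kept the library with less knockdown. The glycolysis mean changed sign without control replicate 1. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 125 ± 1.90 against 70.5 ± 11.7 CPM (log2 change 0.80, SE 0.26) and Plk2 at 15.7 ± 7.08 against 4.78 ± 0.108 CPM, n = 2 each. The primitive endoderm genes Srgn and Sox17 stood at 8.84 ± 5.34 against 17.0 ± 1.19 CPM and 32.0 ± 11.98 against 44.9 ± 0.496 CPM. In the trophectoderm list, Lgals3 stood at 60.5 ± 9.90 against 95.3 ± 31.7 CPM. Asns, which encodes asparagine synthetase and is switched on when amino acids are short, stood at 73.9 ± 13.6 against 158 ± 11.8 CPM.

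With limma, 0 genes passed at late blastocyst (221 unadjusted) and edgeR gave 0 (222 unadjusted). DESeq2 gave 1, Asns (log2 change -1.13, adjusted p = 0.0351). With pairs as a block 3 genes passed (697 unadjusted), within the at most 7 calls of simulations with nothing changed (at least 1 call in 50% of them), each with adjusted p = 0.0479: Asns was lower, and the hypoxia regulator Epas1 (151 ± 57.0 against 78.0 ± 34.3 CPM) and Pmm1 (353 ± 117 against 180.2 ± 7.73 CPM) were higher, Epas1 having been chosen after its values were seen. The blocked fit gave 0 genes without pair 1 and 12 without pair 2, and edgeR with the block gave 0. Without Tdgf1 siRNA replicate 2, limma gave 1 gene, Nupr1 (log2 change -2.67, adjusted p = 0.0179), chosen after its values were seen. Genes that did not pass but whose groups did not overlap included Herpud1 (25.2 ± 8.20 against 61.7 ± 0.129 CPM), Pycr1 (7.48 ± 4.03 against 23.3 ± 5.85 CPM), Mthfd2 (50.04 ± 15.8 against 98.9 ± 2.69 CPM), Wls (26.4 ± 6.41 against 55.8 ± 3.95 CPM), Atg2a (93.9 ± 1.19 against 57.8 ± 8.81 CPM) and Dynlt1a (19.8 ± 6.55 against 3.87 ± 1.66 CPM). Nanog stood at 105.5 ± 13.5 against 82.9 ± 3.10 CPM, Gata6 at 264 ± 27.3 against 196 ± 29.5 CPM and Gata4 at 17.1 ± 13.1 against 21.6 ± 2.69 CPM. The groups did not overlap for 3429 genes (31.9%), where chance gives 33.3% without pairing.

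Of the 16 lists, 5 passed at late blastocyst. The p53 list was higher (adjusted p = 6.35e-09, median 0.44, mean 0.39, 19 of 21 members positive; adjusted p = 0.298 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. With the block, 6 members passed adjusted over the list alone. Without Tdgf1 siRNA replicate 1 its mean was 0.26 and the list still passed. The primitive endoderm list was lower (adjusted p = 0.000157, median -0.28, 17 of 20 negative; adjusted p = 0.353 with an estimated correlation), with 0 and 0 members. Its call was lost with a filter at 5 (mean -0.18 in place of -0.29, adjusted p = 0.143) and without Tdgf1 siRNA replicate 1 (0.05, adjusted p = 0.715), the library that scored lower than the others of its stage on the first principal component, and the mean was -0.63 without Tdgf1 siRNA replicate 2. The trophectoderm list was lower (adjusted p = 0.0231, median -0.14, mean -0.15, 21 of 27 negative; adjusted p = 0.663 with an estimated correlation), with 0 and 0 members, and was lost with a pseudocount of 0.1 (adjusted p = 0.0641), no filter (0.227), a filter at 5 (0.124), quantile normalization (0.0617), without control replicate 1 (mean -0.04, adjusted p = 0.400) and without Tdgf1 siRNA replicate 1 (-0.01, adjusted p = 0.919). Its mean was -0.25 without control replicate 2 and -0.28 without Tdgf1 siRNA replicate 2.

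The stress and unfolded protein response list was lower at late blastocyst (adjusted p = 0.0181, median -0.03, mean -0.16; adjusted p = 0.298 with an estimated correlation), although 10 members were positive and 11 negative. Over all genes 0 members fell, and adjusted over the list alone 3 fell: Asns, Herpud1 and Trib3 (13.0 ± 3.64 against 34.98 ± 4.09 CPM). The call was lost with a filter at 5 (mean -0.09, adjusted p = 0.158), without Tdgf1 siRNA replicate 1 (-0.13, adjusted p = 0.114) and without control replicate 2 (-0.05, adjusted p = 0.859), and the mean was -0.27 without control replicate 1. The glycolysis list was lower (adjusted p = 0.0379, median -0.12, mean -0.10, 13 of 18 negative; adjusted p = 0.646 with an estimated correlation), with 0 and 0 members, and was lost with a pseudocount of 0.1 (0.0574), no filter (0.228), a filter at 5 (0.182), quantile normalization (0.0761), without control replicate 1 (mean 0.02, adjusted p = 0.491) and without Tdgf1 siRNA replicate 1 (-0.04, adjusted p = 0.509), with a mean of -0.23 without control replicate 2 and -0.17 without Tdgf1 siRNA replicate 2. The epiblast list was higher with the block (adjusted p = 0.0200; adjusted p = 0.518 with the block and an estimated correlation) and not without it (0.0635). The remaining lists had 0 members past the threshold over all genes and 0 adjusted over the list alone: Nodal (adjusted p = 0.467), FGF and ERK (0.239), Wnt (0.377), Hippo and Notch (0.200), maternal (0.467), interferon (0.200), cell cycle G2/M (0.777), sterol synthesis (0.368), DNA methylation (0.620) and sex-linked composition (0.777). Cell cycle G2/M and sex-linked composition ranked lower with medians of 0.03 each. Sterol synthesis was called higher without Tdgf1 siRNA replicate 1 (mean 0.53, adjusted p = 7.83e-12) and without control replicate 2 (0.35, adjusted p = 1.59e-05).

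Averaged over the 3 stages, the p53 target and epiblast lists ranked higher in Tdgf1 siRNA embryos and the cell cycle, primitive endoderm and glycolysis lists lower, with 0 single members past the threshold over all genes. All 5 list calls were lost in the stricter test (adjusted p = 0.365 to 0.705 with an estimated correlation), and glycolysis also with the block (adjusted p = 0.0738). The primitive endoderm mean was no longer negative without late blastocyst Tdgf1 siRNA replicate 1, as given below. Plk2 had a log2 change of 0.72 (SE 0.32) and Eda2r of 0.39 (SE 0.23), each higher in 5 of 6 pairs. The epiblast regulator Esrrb had 0.40 (SE 0.15), higher in 5 of 6 pairs, and Hmmr -0.21 (SE 0.10). With limma 0 genes passed (268 unadjusted), with the block 0 (916 unadjusted, smallest adjusted p = 0.0995), with edgeR 0 (304 unadjusted), with DESeq2 0 and with edgeR and the block 1, Rpl17-ps5 (log2 change -2.64, adjusted p = 0.0280). Without pair 1 or 2 the blocked average gave 5 and 8 genes for the morula pairs, 0 and 9 for the early blastocyst pairs and 0 and 1 for the late blastocyst pairs. Genes with the smallest unadjusted p that did not pass were Gm10244 (0.39, SE 0.08), Prrc2a (0.47, SE 0.12) and Atg2a (0.33, SE 0.09) on the higher side, and Herpud1 (-0.61, SE 0.15), Idh2 (-0.36, SE 0.11), Wls (-0.47, SE 0.14) and Smpdl3a (-0.38, SE 0.12) on the lower side.

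In the average, 5 of 16 lists passed, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. The p53 list was higher (adjusted p = 3.83e-05, median 0.21, 18 of 21 positive; adjusted p = 0.365 with an estimated correlation) and was lost without early blastocyst control replicate 1 (mean 0.13 in place of 0.19, adjusted p = 0.0749), with a mean of 0.12 without morula Tdgf1 siRNA 2. Cell cycle G2/M was lower (adjusted p = 0.000561, median -0.08, 23 of 28 negative; adjusted p = 0.365 with an estimated correlation) and was lost without morula control replicate 1 (mean -0.04, adjusted p = 0.193). The epiblast list was higher (adjusted p = 0.0389, median 0.07, 17 of 23 positive; adjusted p = 0.365 with an estimated correlation). It was lost without morula control 1, morula Tdgf1 siRNA 2, early blastocyst control 1, the library labelled early blastocyst Tdgf1 siRNA replicate 2, late blastocyst control 2 or late blastocyst Tdgf1 siRNA 2 (means 0.06 to 0.10 in place of 0.09, adjusted p = 0.116 to 0.238). Primitive endoderm was lower (adjusted p = 0.0389, median -0.12, 14 of 20 negative; adjusted p = 0.705 with an estimated correlation). It was lost without replicate 1 of either morula group, early blastocyst control 1, the library labelled early blastocyst Tdgf1 siRNA replicate 2 or late blastocyst control 1 (means -0.10 to -0.07, adjusted p = 0.122 to 0.307), or late blastocyst Tdgf1 siRNA 1 (mean 0.00298, adjusted p = 0.932), with a mean of -0.22 in place of -0.11 without late blastocyst Tdgf1 siRNA 2. Glycolysis was lower (adjusted p = 0.0475, median -0.07, 12 of 18 negative; adjusted p = 0.705 with an estimated correlation), was not called with the block (adjusted p = 0.0738), and was lost without replicate 1 of either morula group, early blastocyst control 1, the library labelled early blastocyst Tdgf1 siRNA replicate 2 or replicate 1 of either late blastocyst group (means -0.05 to -0.01, adjusted p = 0.223 to 0.435). Its mean of -0.07 was -0.12 without early blastocyst Tdgf1 siRNA 1, -0.13 without early blastocyst control 2 and -0.11 without late blastocyst control 2. Of these lists, only p53 passed without the early blastocyst stage. The stress list did not pass (adjusted p = 0.0673), although 2 of its members fell adjusted over the list alone and 0 over all genes. With the block, the members that passed adjusted over the list alone were 8 for stress, 5 for p53 and 1 for trophectoderm. The other 10 lists had adjusted p = 0.477 to 0.883, with trophectoderm and Wnt ranked lower at medians of 0.03 each and sterol synthesis lower at a mean of 0.01. With fry, 0 lists passed in any siRNA comparison.

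The p53 target list, which ranked higher at morula and late blastocyst, had a mean of -0.08 at early blastocyst, and its differences between neighbouring stages passed at the preset correlation. They were lost in the stricter test (adjusted p = 0.727 and 0.337 with an estimated correlation), and at morula the mean was 0.05 without Tdgf1 siRNA replicate 2. The early blastocyst pairs went opposite ways (list means 3.10 against 3.05 and 3.20 against 3.41), and the mean there was 0.10 without control replicate 2, -0.26 without control replicate 1, -0.03 without Tdgf1 siRNA replicate 1 and -0.13 without the library labelled early blastocyst Tdgf1 siRNA replicate 2. Cdkn1a and Plk2 at late blastocyst stood above control as given, while at early blastocyst the p53 target Trp53inp1 stood at 36.9 ± 4.07 against 55.2 ± 19.7 CPM, n = 2 each. The difference between early blastocyst and morula was -0.34 (adjusted p = 3.69e-05; adjusted p = 0.727 with an estimated correlation) and that between late and early blastocyst 0.47 (adjusted p = 5.13e-09; adjusted p = 0.337 with an estimated correlation). For single genes, limma's test over the 3 stages gave 0 genes (97 unadjusted) and edgeR 0 (137 unadjusted), while DESeq2 was not run for it. With the block it gave 1, Gm12621 (adjusted p = 0.0342, 475 unadjusted), and with edgeR and the block 2, Gm12621 and Gm12625 (adjusted p = 0.0116 each). For single differences between stages limma gave 0 genes each (131 unadjusted for early blastocyst minus morula, 127 for late minus early blastocyst and 148 for late blastocyst minus morula), and edgeR and DESeq2 calls were not counted for them. With the block, 4 were lower for early blastocyst minus morula (Gm12621, Gm12625, Gm12627 and Tpm3-rs7; 445 unadjusted) and 0 passed for late minus early blastocyst (469 unadjusted). It gave 3 for late blastocyst minus morula (4930550L24Rik and Asns lower, Ly6a higher, adjusted p = 0.0343 each; 477 unadjusted), of which 4930550L24Rik and Ly6a were chosen after their values were seen. These early blastocyst differences draw on the library labelled early blastocyst Tdgf1 siRNA replicate 2. With the block, further lists passed for the difference between early blastocyst and morula (epiblast, adjusted p = 0.0362 against 0.165, and sterol synthesis, 0.00449 against 0.253), between late and early blastocyst (trophectoderm, 0.00938 against 0.125) and between late blastocyst and morula (sterol synthesis, 0.00116 against 0.0975). With the block and an estimated correlation these were lost (adjusted p = 0.857 for epiblast and sterol synthesis of the first difference, 0.954 for trophectoderm and 0.528 for sterol synthesis of the last).

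**Figure D3:**
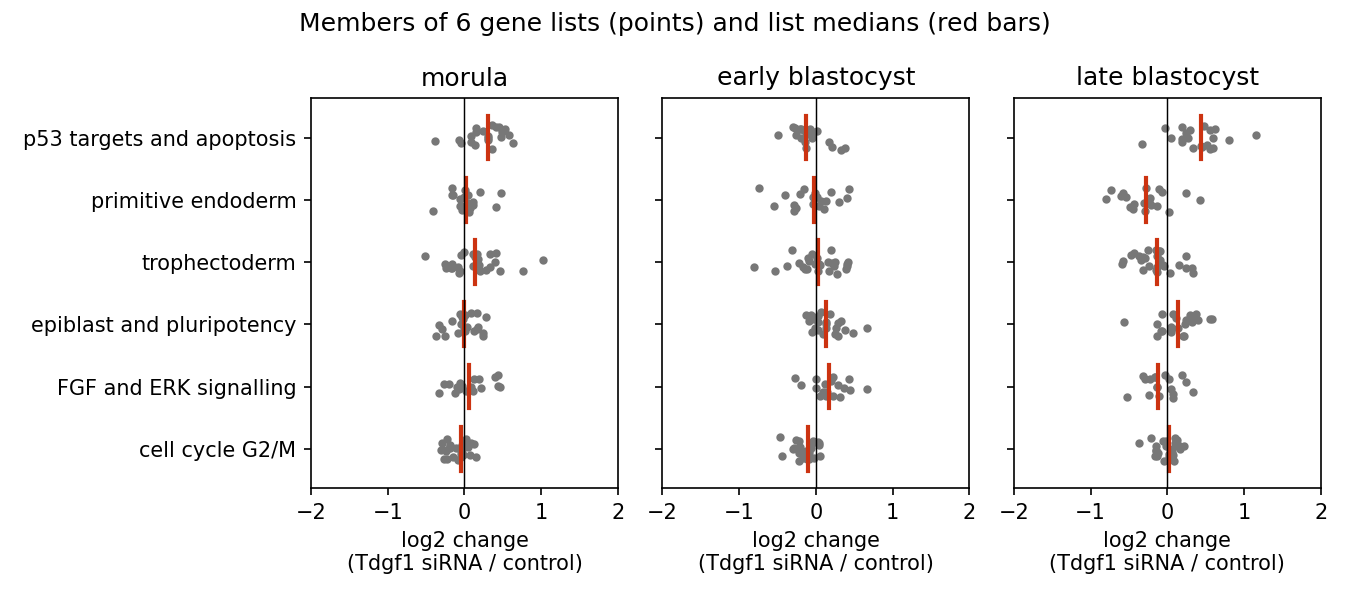
Log2 change of each tested member (points) of 6 gene lists, Tdgf1 siRNA over control, at each stage. Red bars give the list medians.

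From morula to early blastocyst in controls, the lists of the trophectoderm, the epithelium that forms the blastocyst wall, and of glycolysis ranked higher, with 12 of 27 and 12 of 18 members rising over all genes. Both list calls were lost in the stricter test (adjusted p = 0.857 with an estimated correlation). Levels here are early blastocyst first. The keratins Krt18 and Krt8 stood at 1041 ± 616 against 119 ± 59.7 CPM and 1190.1 ± 672 against 200.04 ± 73.9 CPM, and Dppa1 at 238 ± 131 against 9.86 ± 2.72 CPM, n = 2 each. Lgals1 rose from 7.83 ± 2.63 to 213 ± 123 CPM (log2 change 4.14, SE 0.32, adjusted p = 3.46e-05) and Adh1 from 0.610 ± 0.325 to 146 ± 148 CPM. The glycolytic gene Gapdh rose from 125 ± 19.97 to 649 ± 112 CPM, and the naive pluripotency factor Klf2 fell from 109 ± 42.8 to 37.4 ± 1.61 CPM. Ass1 rose (244 ± 59.8 against 29.1 ± 14.4 CPM), and the ion transporter gene Slc12a2 fell (35.3 ± 19.1 against 244 ± 62.1 CPM), as did the chaperone gene Dnajb9 (34.4 ± 17.0 against 150.2 ± 60.001 CPM). Tdgf1 itself did not pass (17.4 ± 6.13 against 26.4 ± 4.26 CPM, adjusted p = 0.202), nor did Nanog (adjusted p = 0.388).

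In all, 1702 genes passed from morula to early blastocyst, 1023 higher and 679 lower (3290 unadjusted). edgeR gave 1702, of which 1496 were shared, and DESeq2 2203, of which 1620 were shared, all in the same direction. The higher share was 60.1%, against 52.0% with quantile normalization and 54.6% with median-of-ratios scaling. Fewer passed with no filter (462) and without morula control replicate 1 (668), morula control replicate 2 (789) or early blastocyst control replicate 1 (294). Of 64 calls of named genes, 25 were kept with each library left out in turn. The groups did not overlap for 6175 genes (57.4%), where chance gives 33.3%. The trophectoderm list rose (adjusted p = 5.25e-05, median 1.22; adjusted p = 0.857 with an estimated correlation), with 12 members rising, 2 falling and 13 not passing over all genes, and 15 rising and 2 falling adjusted over the list alone. Its mean of 1.04 was 0.69 without early blastocyst control replicate 1. Glycolysis rose (adjusted p = 5.25e-05, median 0.84; adjusted p = 0.857 with an estimated correlation), with 12 rising, 0 falling and 6 not passing over all genes and 12 and 0 adjusted over the list alone, and was the 1 list that passed with fry (adjusted p = 0.0393; trophectoderm 0.0654). No other list passed (adjusted p = 0.377 to 0.892).

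Members of the other lists moved singly from morula to early blastocyst, given here as rising and falling over all genes and then adjusted over the list alone. Epiblast had 2 and 4 (4 and 5), primitive endoderm 3 and 1 (3 and 1), Nodal 3 and 2 (4 and 2), FGF and ERK 1 and 1 (1 and 1), Wnt 3 and 0 (4 and 0), Hippo and Notch 1 and 0 (0 and 0), maternal 2 and 0 (2 and 0) and p53 1 and 1 (1 and 1). Stress had 3 and 2 (3 and 2), interferon 0 and 1 (0 and 1), cell cycle G2/M 1 and 0 (1 and 0), sterol synthesis 3 and 0 (3 and 0), DNA methylation 3 and 0 (3 and 0) and sex-linked composition 1 and 1 (4 and 2). FGF and ERK, p53 and cell cycle G2/M ranked lower with positive medians (0.07, 0.05 and 0.04), and sex-linked composition lower with a median of -0.13 and a mean of 0.16. Of the untested 2-cell list, Sp110 fell (log2 change -2.05, SE 0.60). That call was lost with edgeR, with DESeq2 and with no filter. It was also lost without morula control replicate 2 or early blastocyst control replicate 1 (log2 changes from -2.75 to -1.35 over the libraries left out).

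From early to late blastocyst in controls, as the inner cell mass separates into its lineages, the primitive endoderm and trophectoderm lists ranked higher, with 16 of 20 and 20 of 27 members rising over all genes. The epiblast list ranked lower, with 9 of 23 members falling and 4 rising. All 3 list calls were lost in the stricter test (adjusted p = 0.371 with an estimated correlation), and that of epiblast also with quantile normalization or median-of-ratios scaling. The stricter test passed 0 lists here although most primitive endoderm and trophectoderm members rose singly, so it had little power to detect such changes. Levels here are late blastocyst first. The endoderm regulators Sox17 and Gata4 rose to 44.9 ± 0.496 from 0.797 ± 0.510 CPM and to 21.6 ± 2.69 from 0.766 ± 0.149 CPM, n = 2 each. The trophectoderm genes Plac1 and Eomes rose to 194 ± 46.5 from 1.78 ± 0.874 CPM and to 197 ± 10.2 from 24.5 ± 21.8 CPM. Nanog fell to 82.9 ± 3.10 from 360 ± 95.6 CPM (log2 change -2.05, SE 0.24) and Pou5f1 to 120.2 ± 17.5 from 360.2 ± 70.6 CPM. Tdgf1 rose (90.9 ± 8.94 against 17.4 ± 6.13 CPM, log2 change 2.20, SE 0.27, adjusted p = 0.000137). The largest rises among genes with separate groups were those of BC051665 (1238 ± 550.1 against 0.301 ± 0.191 CPM) and Tmsb4x (1449 ± 42.3 against 28.0 ± 33.0 CPM), and Isyna1 (176 ± 27.1 against 1876 ± 541 CPM) and Cited1 (7.42 ± 3.36 against 88.6 ± 20.1 CPM) fell. Dppa3 fell (1028 ± 81.2 against 4249 ± 1629 CPM), and the Wnt antagonist Dkk1 rose (34.9 ± 6.003 against 0.699 ± 0.064 CPM). The stress genes Asns, Herpud1, Trib3 and Ddit3 rose (log2 changes 2.32, 2.04, 1.97 and 1.71).

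In all, 2979 genes passed from early to late blastocyst, 1775 higher and 1204 lower (4254 unadjusted). edgeR gave 2828, of which 2577 were shared, and DESeq2 3290, of which 2821 were shared, all in the same direction. The higher share of 59.6% depended on scaling (48.2% with quantile normalization, 49.8% with median-of-ratios scaling), and the median log2 change of all genes went from 0.08 to -0.05 with quantile normalization. Fewer passed without early blastocyst control replicate 2 (1211), late blastocyst control replicate 1 (1261) or late blastocyst control replicate 2 (1709), and of 81 calls of named genes 52 were kept with each library left out in turn. The groups did not overlap for 7194 genes (66.9%), where chance gives 33.3%.

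Of the 16 lists, 5 passed from early to late blastocyst. Primitive endoderm rose (adjusted p = 2.36e-08, median 1.72; adjusted p = 0.371 with an estimated correlation), with 16 members rising, 0 falling and 4 not passing over all genes and 17 and 0 adjusted over the list alone. Trophectoderm rose (adjusted p = 6.75e-08, median 1.46; adjusted p = 0.371 with an estimated correlation), with 20 rising, 2 falling and 5 not passing, and 21 and 2 adjusted over the list alone. Wnt signalling rose (adjusted p = 0.00594, median 0.54; adjusted p = 0.461 with an estimated correlation), with 6 rising, 0 falling and 6 not passing, and 6 and 0 adjusted over the list alone. Epiblast fell (adjusted p = 0.0479, median -0.29; adjusted p = 0.371 with an estimated correlation), with 4 rising, 9 falling and 10 not passing, and 5 and 9 adjusted over the list alone. That call was lost with quantile normalization (0.107), median-of-ratios scaling (0.0574) and without late blastocyst control replicate 2 (mean -0.27 in place of -0.35, adjusted p = 0.0949). Cell cycle G2/M fell (adjusted p = 0.0479, median -0.15; adjusted p = 0.461 with an estimated correlation), with 0 rising, 7 falling and 21 not passing, and 0 and 7 adjusted over the list alone, and was lost with a pseudocount of 0.1 (0.0554), a filter at 5 (0.159), quantile normalization (0.238), the controls alone (0.0611), the number as a block (0.0560), without early blastocyst control replicate 2 (0.104) and without late blastocyst control replicate 1 (0.0829), with means of -0.17 to -0.15 in place of -0.17.

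Of the remaining lists, members that rose and fell from early to late blastocyst over all genes, and then adjusted over the list alone, were 4 and 0 (4 and 0) for Nodal, 6 and 1 (6 and 1) for FGF and ERK, 3 and 2 (4 and 3) for Hippo and Notch, 1 and 2 (1 and 3) for maternal and 2 and 3 (2 and 2) for p53. They were 5 and 1 (5 and 2) for stress, 0 and 1 (0 and 1) for interferon, 5 and 2 (6 and 3) for glycolysis, 1 and 0 (0 and 0) for sterol synthesis, 6 and 0 (6 and 0) for DNA methylation and 2 and 0 (2 and 0) for sex-linked composition. These 11 lists had adjusted p = 0.133 to 0.605, and p53 ranked lower with a mean of 0.04. With fry 8 lists passed: epiblast, primitive endoderm, trophectoderm, Nodal, FGF and ERK, Wnt, stress and sex-linked composition. Of the untested lists, Serpine2 and Vim rose (log2 changes 1.94 and 1.80) and Amhr2 and Cd74 fell (-1.35 and -1.95), calls lost for Amhr2 without early blastocyst control replicate 2 and for Cd74 without that library or either late blastocyst control (log2 changes from -1.75 to -0.96 for Amhr2 and from -2.44 to -1.45 for Cd74).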

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

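The test of whether 1 library sets the p53 value, the test of a lag for the p53 list and the timing values with 1 library left out were chosen only after the results were seen, and the tests of developmental timing and of pseudogene identity were set before their outcome was computed. What singled out the 8 results of this part was a test of the difference of the Tdgf1 siRNA effect between stages. The p53 list gave -0.34 for early blastocyst minus morula (adjusted p = 3.69e-05) and 0.47 for late minus early blastocyst (adjusted p = 5.13e-09). For late minus early blastocyst, primitive endoderm gave -0.23 (adjusted p = 0.02496), FGF and ERK -0.25 (adjusted p = 0.00278) and cell cycle G2/M 0.14 (adjusted p = 0.0178). For late blastocyst minus morula, primitive endoderm gave -0.32 (adjusted p = 0.00780) and trophectoderm -0.28 (adjusted p = 0.0112). The pseudogene Gm12621 gave adjusted p = 0.0342 over the 3 stages with the block. With an estimated correlation none of the 7 list differences passed: p53 had adjusted p = 0.727 and 0.337, primitive endoderm 0.770 and 0.592, FGF and ERK 0.337, cell cycle G2/M 0.548 and trophectoderm 0.646.

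Most of these calls were lost with a library left out, some with a mean as large as before. The p53 difference of early blastocyst minus morula was lost without morula control replicate 2 (-0.25, adjusted p = 0.0706), morula Tdgf1 siRNA replicate 2 (-0.13, 0.328) or early blastocyst control replicate 2 (-0.17, 0.349), and was -0.56 without morula Tdgf1 siRNA replicate 1 and -0.52 without early blastocyst control replicate 1. That of late minus early blastocyst passed with each library left out, lowest without early blastocyst control replicate 2 (0.29). For late minus early blastocyst, primitive endoderm was lost without early blastocyst Tdgf1 siRNA replicate 1 (-0.15, 0.0878), early blastocyst control replicate 2 (-0.10, 0.164), the library labelled early blastocyst Tdgf1 siRNA replicate 2 (-0.30, 0.110), late blastocyst control replicate 1 (-0.15, 0.153) or late blastocyst Tdgf1 siRNA replicate 1 (0.11, 0.441), and was -0.35 without early blastocyst control replicate 1 and -0.56 without late blastocyst Tdgf1 siRNA replicate 2. FGF and ERK was lost without early blastocyst Tdgf1 siRNA replicate 1 (-0.15, 0.0798) or early blastocyst control replicate 2 (-0.12, 0.0787), and was -0.38 without early blastocyst control replicate 1. Cell cycle G2/M was lost without early blastocyst Tdgf1 siRNA replicate 1 (0.13, 0.248), early blastocyst control replicate 2 (0.14, 0.290) or replicate 1 of the late blastocyst controls (0.12, 0.145) or Tdgf1 siRNA libraries (0.12, 0.0888), so its mean hardly moved from 0.14. For late blastocyst minus morula, primitive endoderm was lost without replicate 2 of the morula controls (-0.24, 0.0838) or Tdgf1 siRNA libraries (-0.28, 0.0558), late blastocyst control replicate 1 (-0.24, 0.0517) or late blastocyst Tdgf1 siRNA replicate 1 (0.02, 0.790), and was -0.65 without late blastocyst Tdgf1 siRNA replicate 2. Trophectoderm was lost without replicate 1 of the morula controls (-0.31, 0.0701), morula Tdgf1 siRNA (-0.20, 0.114), late blastocyst controls (-0.17, 0.174) or late blastocyst Tdgf1 siRNA (-0.14, 0.410).

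The p53 list may differ for a technical reason, 1 library, or a biological one, the siRNA or slower development. At morula 1 library could account for the value: without Tdgf1 siRNA replicate 2 the mean fell from 0.264 to 0.0473, and the first pair stood at 3.37 (Tdgf1 siRNA) against 3.42. At late blastocyst no library left out removed the difference. The lowest mean was 0.26 of 0.39, without Tdgf1 siRNA replicate 1, and both pairs were higher (3.79 against 3.23 and 3.53 against 3.31). The limit used to judge this was set after the values were seen, so a contribution of Tdgf1 siRNA replicate 1 is not excluded. Slower development could not be told from these data, because the list mean differed by 0.0381 (SE 0.109) from early to late blastocyst in controls. That SE was taken over the 21 members of the list, which can move together, and not over libraries. In the average, 15 of 100 splits of the libraries gave as large a mean (0.19, highest other 0.31), so chance is not excluded there. This split count had no prediction set beforehand.

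Whether late blastocyst Tdgf1 siRNA embryos lag behind controls, which would lower primitive endoderm and trophectoderm values, is left open. Asns, Herpud1 and Trib3, lower with the siRNA, also rose from early to late blastocyst in controls. Cdkn1a, higher with the siRNA, fell in controls (log2 changes from -1.24 to -0.39 over the libraries left out). These genes are therefore not separate from the timing question. They were compared after their values were seen. Of genes that changed from morula to early blastocyst in controls, the 1023 that rose had a median effect at late blastocyst 0.20 below that of the 679 that fell (-0.20). Random lists matched on expression (-0.02 to 0.02) cannot judge this, because genes of a stage move together within a library, and at early blastocyst the values with 1 library left out lay outside such ranges in both directions (-0.25 to 0.22). Scores of the libraries on those 1023 and 679 genes were 1.10 and 1.31 with Tdgf1 siRNA against 1.34 and 1.47, so each pair was lower, as collection of younger embryos would also give. The lowest score is that of Tdgf1 siRNA replicate 1, without which the timing difference was -0.08 and the primitive endoderm mean 0.05. That library also had the stronger knockdown, with Tdgf1 at 50.9% of its control against 83.6% for replicate 2.

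The pseudogene cluster on chromosome 11 may stand for 1 signal and not 4. The least similar pair of its transcripts is 99.2% identical, so reads could be shared between copies. Whether Tdgf1 siRNA embryos were ahead at early blastocyst is left open, because the first pair was behind (-0.813 against -0.692) and the second ahead (-1.11 against -1.21): the 3109 genes that rose from morula to late blastocyst had a median effect slightly below that of the 2069 that fell (-0.0106), and this was 0.22 without control replicate 1, 0.13 without the library labelled early blastocyst Tdgf1 siRNA replicate 2, -0.14 without Tdgf1 siRNA replicate 1 and -0.25 without control replicate 2. By the rule set beforehand a value at or below 0 counted against being ahead, but its sign depended on the library left out. Timing matters here because Gm12621 fell from early to late blastocyst in controls. Each of the 4 pseudogenes was lower in both pairs, so also in the pair that was behind (Gm12621 at 17.8 against 49.6 CPM). A single pair cannot settle the question. No further biological explanation was tested. This direction draws on the library labelled early blastocyst Tdgf1 siRNA replicate 2.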

How the results depend on the processing

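The edgeR, DESeq2 and without-early-blastocyst alternatives were chosen only after the results were seen. Of the gene counts, 99 alternative values lay within 1.5 times of the first and 18 did not. The 99 include cases of 0 genes against 0 genes. In every siRNA comparison the first count was 0, so agreement there says little. For the named genes, 5988 alternative values were counted as unchanged, 247 lost a call, 34 gained one and 0 changed sign with a call. For single lists the numbers were 2040, 157, 50 and 14. Values with no call in either setting were counted as unchanged whatever their sign, so direction was not checked for them. The same holds for genes to which a tool gave no adjusted p. With the replicate block, the count of genes at morula went from 0 to 5, at early blastocyst from 0 to 5, at late blastocyst from 0 to 3 and for the interaction from 0 to 1, and edgeR with the replicate block gave 1, 5, 0 and 2, and 1 for the average. The block also took the lists from 2 to 4 at morula and, for the siRNA effect at early blastocyst minus morula, from 1 to 3. From early to late blastocyst in controls, the number as a block ended the call of cell cycle G2/M (adjusted p = 0.0560). The other list calls and gene counts that the block changed stand beside their results, and it changed no other list call. For the differences between stages it also moved the members that passed adjusted over the list alone: for p53 from 0 to 3 (early blastocyst minus morula and late minus early blastocyst), for trophectoderm from 0 to 1 and from 0 to 4 (early and late blastocyst minus morula) and for stress from 0 to 3, from 1 to 3 and from 1 to 2 (early blastocyst minus morula, late minus early blastocyst, late blastocyst minus morula). In early blastocyst minus morula, primitive endoderm went from 0 to 1, and in late blastocyst minus morula, epiblast went from 0 to 2 and interferon and glycolysis from 0 to 1 each. At late blastocyst, 11 genes passed with no filter (all low, tested among more genes) and 1 with DESeq2. From morula to early blastocyst, 462 genes passed with no filter, against 1702. List counts with an estimated correlation were 0 in every comparison. With fry they were 0 in every siRNA comparison, 1 from morula to early blastocyst and 8 from early to late blastocyst. At morula 1 list passed with quantile normalization. At late blastocyst 3 passed with a pseudocount of 0.1, 3 with no filter, 1 with a filter at 5 and 3 with quantile normalization. For the average, 3 passed with a pseudocount of 0.1, 2 with no filter, and 3 each with a filter at 5, quantile normalization and median-of-ratios scaling, and 1 over morula and late blastocyst only. From early to late blastocyst in controls, 3 passed with a filter at 5 and 3 with quantile normalization. For late minus early blastocyst, 1 passed with no filter, 2 with a filter at 5 and 2 with median-of-ratios scaling, and for late blastocyst minus morula 0 and 1 with no filter and with a filter at 5. The cause was not tested.

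With 1 library left out, a lone library is assumed to vary like the other groups. Gene counts then ranged from 0 to 0 at morula, early blastocyst, the average and the interaction, from 0 to 1 at late blastocyst, from 294 to 1681 from morula to early blastocyst and from 1211 to 2816 from early to late blastocyst. List counts ranged from 0 to 3 at morula, 1 to 4 at early blastocyst, 3 to 7 at late blastocyst, 1 to 6 for the average, 2 to 2 from morula to early blastocyst and 4 to 6 from early to late blastocyst. For the differences between stages they ranged from 0 to 2 (early blastocyst minus morula), 1 to 6 (late minus early blastocyst) and 1 to 4 (late blastocyst minus morula). List means that changed sign, with a call on either side, are given as the range over left-out libraries. Cell cycle G2/M at morula ranged from -0.20 to 0.0223 (highest without control replicate 1), trophectoderm at early blastocyst from -0.34 (without control replicate 2) to 0.36, and glycolysis at late blastocyst from -0.23 to 0.0186 (highest without control replicate 1). Primitive endoderm was highest without late blastocyst Tdgf1 siRNA replicate 1 throughout: it ranged from -0.63 to 0.0458 at late blastocyst, from -0.22 to 0.00298 for the average, from -0.56 to 0.11 for late minus early blastocyst and from -0.65 to 0.0184 for late blastocyst minus morula. Sterol synthesis ranged from -0.66 to 0.53 at late blastocyst, above 0 without Tdgf1 siRNA replicate 1 (0.53) or control replicate 2 (0.35). For the average it ranged from -0.19 to 0.20, called below 0 without late blastocyst Tdgf1 siRNA replicate 2 (-0.19) or control replicate 1 (-0.13). For late minus early blastocyst it ranged from -0.59 to 0.60, below 0 without those same libraries (-0.59 and -0.41), and for late blastocyst minus morula from -0.81 to 0.37, highest without Tdgf1 siRNA replicate 1. The cause was not tested. Depth limits genes near 3 reads. In the simulations with pairs sharing deviations, 2-fold changes within 1 stage were recovered in at most 8% of genes without the block. That share may be too low for the real data.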

Other observations

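The tests on unadjusted counts and on sign flips of pairs below were chosen only after the results were seen. The tests of the gene count and the list count over all splits were set before their outcome was computed. The counts by number of parted pairs had no prediction set beforehand. Sterol synthesis genes followed the replicate number at late blastocyst and not the siRNA. Their summed level was 1318 CPM (control) and 1074 CPM (Tdgf1 siRNA) in replicate 1 and 2722 and 2827 CPM in replicate 2. The sterol enzyme gene Sqle accordingly had a wide spread in each group (92.9 ± 83.5 against 97.4 ± 50.6 CPM, n = 2 each), as did Insig1 (91.1 ± 79.8 against 89.6 ± 24.9 CPM).

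Other splits of the 12 libraries, balanced within stages, could give results as large as the real one for the average over stages. The count of genes past the threshold cannot be tested this way, because the real count is 0 and each of the 100 splits reaches it (100 of 100, highest other 449). With limma, 56 of 100 splits gave as many at an unadjusted p under 0.05 (real 268, highest other 2352) and 14 of 100 gave as many lists (real 5, highest other 6), so chance is not excluded for the list count, and for the unadjusted count these splits ignore the pairs. The splits that called many genes kept same-numbered libraries on 1 side, which points to the pairs as a structure of the samples: up to 449 genes where no pair was parted, 418 where 2 pairs were parted, 28 where 4 were, and 0 in the 30 splits that, like the real one, part all 6 pairs. Among those 30 the real unadjusted count of 268 was the highest (highest other 203), while the list count of 5 was not (highest other 6). With the block, 1 of 32 sign flips of pairs, the real one, gave as many genes at an unadjusted p under 0.05 (916, highest other 770). That is the smallest share these flips can give. The test was chosen after the results were seen, and the pairs were taken from these same data, so it cannot exclude chance. After adjustment 0 genes passed.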
